A study of Homo sapiens with 8 samples.

How the data were processed

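The series comprises 8 MNase-seq libraries of Kasumi-1 cells with degron-tagged SMARCA5, 2 per group at 0, 2, 6 and 24 h of 500 nM dTAG-47. The submitters' processing notes name Trimmomatic 0.32, Bowtie2, SAMtools and deepTools for the series, and hg19 as the genome build. The notes tie none of these tools to the list of motif positions.

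The only processed file used here is that list. Per the file headers it gives a chromosome, a start, a stop and a strand for each position, and the deposited values are coordinates with no score, p-value or peak identifier. The name of the deposited list speaks of FIMO (a motif scanner), CTCF, a q-value of 0.01 and overlap with peaks. It also speaks of a peak identifier, although the list has no column for one. The scanner's version and motif matrix, the source of the peaks and any selection among positions of one peak are not given in the sources used here. Replicate error does not enter any value, since the list belongs to the whole series and its lines are not samples. Every position spans 19 bases when both ends are counted, and coordinates are printed as deposited. Whether they count from 0 or from 1 could not be tested without a genome, so a position may be off by 1 base. The build was taken as hg19 from the submitters' processing notes and was not checked against chromosome lengths.

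The list was read as deposited; it held no repeated line, so no position was removed. Sites were ordered along each chromosome, and the distance between neighbours was the difference of their starts. A neighbouring pair was called same-strand, convergent (plus then minus) or divergent (minus then plus), and was placed in 1 of 5 distance ranges with limits at 1 kb, 10 kb, 100 kb and 1 Mb. The share of plus sites was tested with a two-sided exact binomial test. Orientation was tested with a two-sided permutation test that shuffled strands within each chromosome 100000 times, with Benjamini-Hochberg adjustment over the 5 ranges. Intervals are 95% Wilson intervals. They treat sites as independent and cover counting error only. Densities are counts per Mb between the first and the last site of a chromosome. Dense windows were chosen as the 5 non-overlapping 100 kb windows with the most sites, each starting at a site, and gaps as the 5 widest. That rule for named regions, the ranges, the tests and most alternatives were fixed before the data were examined. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

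The shuffle test was tested on simulated data: strands drawn at the 22643 real positions, 60 times without and 60 times with a planted orientation. With random strands the convergent share was called in 1 of 60 simulations at 100 kb to 1 Mb and in 0 of 60 at 1 to 10 kb. A difference of 20 points between the switch rates was then planted at 100 kb and over, and of -20 points under 10 kb. The convergent share was called in 60 of 60 at 1 to 10 kb and in 60 of 60 at 100 kb to 1 Mb. Where pairs were few, the planted difference was mostly missed: it was called in 5 of 60 under 1 kb and in 8 of 60 over 1 Mb. However, 38 of 60 simulations also called the range from 10 to 100 kb, where nothing had been planted, because convergent and divergent pairs alternate. A second test was therefore added: the percentage of plus sites followed by a minus site against the percentage of minus sites followed by a plus site, with Fisher's exact test. It called the unplanted range in 0 of 60 of the planted simulations and recovered mean differences of -20.2 points at 1 to 10 kb and 20.2 points at 100 kb to 1 Mb.

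The planned test of nucleosome signal at these sites after dTAG-47 was not run, because the list has no values per library. Position relative to genes, 12 fixed gene lists, motif sequence and density per chromosome length needed an hg19 genome or annotation and were not analysed here. Sequencing depth per library is unknown from the list.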

Results

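The study asked how nucleosomes respond when SMARCA5, an ATPase of the ISWI family of chromatin remodellers, is removed quickly from Kasumi-1 cells. Kasumi-1 is a human acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion. Both SMARCA5 alleles carried an FKBP12 degron tag, so that the degrader molecule dTAG-47 could direct the protein to destruction. Nucleosomes were mapped by MNase-seq, in which micrococcal nuclease digests the linker DNA and the protected mononucleosomes are sequenced. The 8 libraries fall into 4 groups of 2: untreated cells (0 h) and cells given 500 nM dTAG-47 for 2, 6 or 24 h. The data used here are the reference points of such a study, a single list of CTCF motif positions. CTCF is the zinc-finger protein that blocks cohesin at chromatin loop anchors, and nucleosomes form regular arrays on both sides of its bound sites. The list has 4 columns and 0 columns with values per library. Nucleosome signal, its depth and its change after 2, 6 or 24 h of dTAG-47 were therefore not analysed here, and the comparisons below concern the sites themselves.

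The list placed CTCF motifs throughout the genome, with by far the densest cover on the chromosomes 19, 22 and 17. It held 22643 distinct positions of 19 bases each on 24 chromosomes of hg19. Chromosome 1 had the most sites, 2262, which was 9.99% of the list. Relative to the stretch between the first and the last site, chromosome 19 had 18.997 ± 0.568 sites per Mb (Poisson standard error of the count), chromosome 22 had 15.3 ± 0.67 and chromosome 17 had 15.1 ± 0.43. Among chromosomes 1 to 22 and X, chromosome X was at the other end with 3.27 ± 0.15 sites per Mb, and chromosome 19 was 5.80-fold denser than it. Chromosomes 13 and 4 were also sparse, at 4.23 ± 0.21 and 5.07 ± 0.16 sites per Mb. Chromosome Y held 2 sites. The densities of chromosomes 22 and 17 differed by less than their counting errors, while chromosome 19 lay above both and chromosomes X, 13 and 4 lay below both by several times these errors. Such errors treat sites as independent and may be too small, since spacings departed from uniform random placement (given below). The stretch between end sites is shorter than the chromosome and no test against chromosome length was made.

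**Figure D1:**
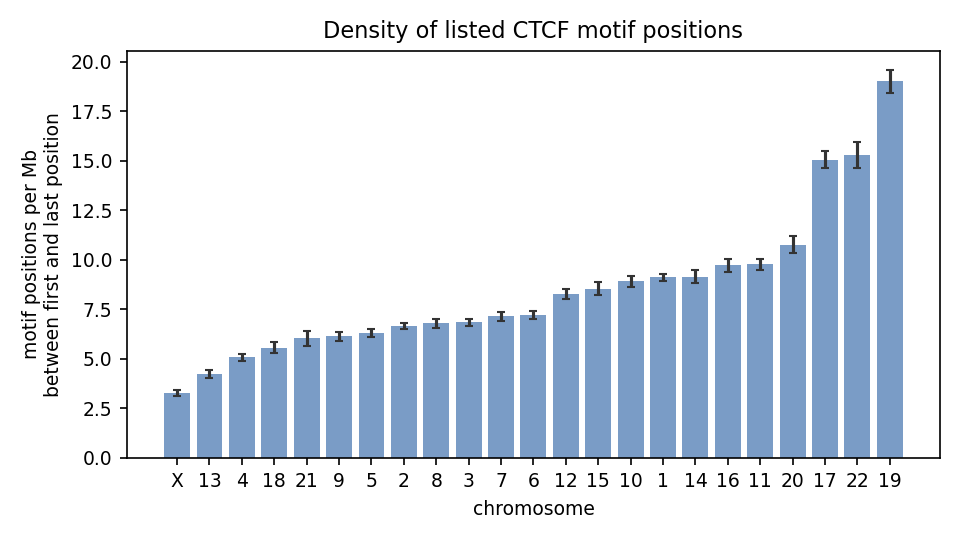
Listed CTCF motif positions per Mb between the first and the last position of each chromosome (hg19), chromosomes ordered by density, error bars the Poisson standard error of the count. Chromosome X is lowest at 3.27 per Mb and chromosome 19 highest at 18.997 per Mb; chromosome Y, with 2 positions, is not drawn.

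Neither strand was preferred. The plus strand held 11292 sites and the minus strand 11351, so 49.9% were on the plus strand (95% Wilson interval 49.2% to 50.5%; two-sided exact binomial p = 0.70). On chromosomes 1 to 22 and X the plus share ran from 46.96% on chromosome 21 to 53.0% on chromosome 18. No chromosome passed the exact binomial test after Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.99, and 0 chromosomes had an unadjusted p under 0.05.

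Listed sites were mostly solitary at the scale of a nucleosome array. The median distance between neighbouring sites was 49.2 kb, the quartiles were 17.7 and 126 kb, and no positions overlapped. The closest pair lay 351 bp apart. A second site within 1 kb was found for 44 of the 22643 sites, or 0.194% (95% Wilson interval 0.145% to 0.261%). Within 2 kb the number was 730, or 3.22% (3.002% to 3.462%), within 10 kb it was 6036, or 26.7%, and within 100 kb it was 19709, or 87.0%. An average profile drawn 1 kb to each side of these motifs would thus contain a second listed site for 0.194% of them. Motifs that an upstream selection may have removed are not counted, so the share with any second motif is unknown.

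The relative orientation of neighbouring motifs depended on how far apart they lay. Pairs facing each other (convergent, plus then minus along the chromosome) were the minority of opposite-strand pairs at short range and the majority at long range, with the change at 50 to 100 kb. From 1 to 10 kb there were 560 convergent and 987 divergent pairs, a convergent share of 36.2% (95% Wilson interval 33.8% to 38.6%). From 100 kb to 1 Mb there were 2197 convergent and 1285 divergent pairs, a share of 63.1% (61.5% to 64.7%). Convergently oriented motifs are the arrangement known from CTCF-anchored chromatin loops.

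The intermediate and the largest distances fitted between or beyond these values. From 10 to 100 kb the convergent share was 45.4% (44.2% to 46.7%; 2805 convergent, 3369 divergent), and over 1 Mb it was 69.3% (62.4% to 75.4%; 131 convergent, 58 divergent). With strands shuffled within chromosomes, the mean share in these 4 ranges was 50.0%, with standard deviations of 1.12 points at 1 to 10 kb, 0.413 at 10 to 100 kb, 0.688 at 100 kb to 1 Mb and 3.55 over 1 Mb. In each of the 4 ranges the two-sided permutation p was the smallest that 100000 shuffles can give, 1e-05, which became 1.25e-05 after Benjamini-Hochberg adjustment over the 5 ranges. Under 1 kb, 22 pairs were too few: the share was 62.5% (30.6% to 86.3%; permutation adjusted p = 0.44). Over all distances the counts were nearly equal, 5698 convergent and 5702 divergent pairs (49.98% convergent, permutation p = 0.28). This equality is built in, because both kinds must alternate along a chromosome. It also ties the ranges, since an excess of convergent pairs in some must be nearly matched by a deficit in others. Their tests are therefore not independent. Which pairs are named convergent rests on the direction of the motif matrix, which is not given in the sources used here; with the opposite direction the 2 names would exchange.

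**Figure D2:**
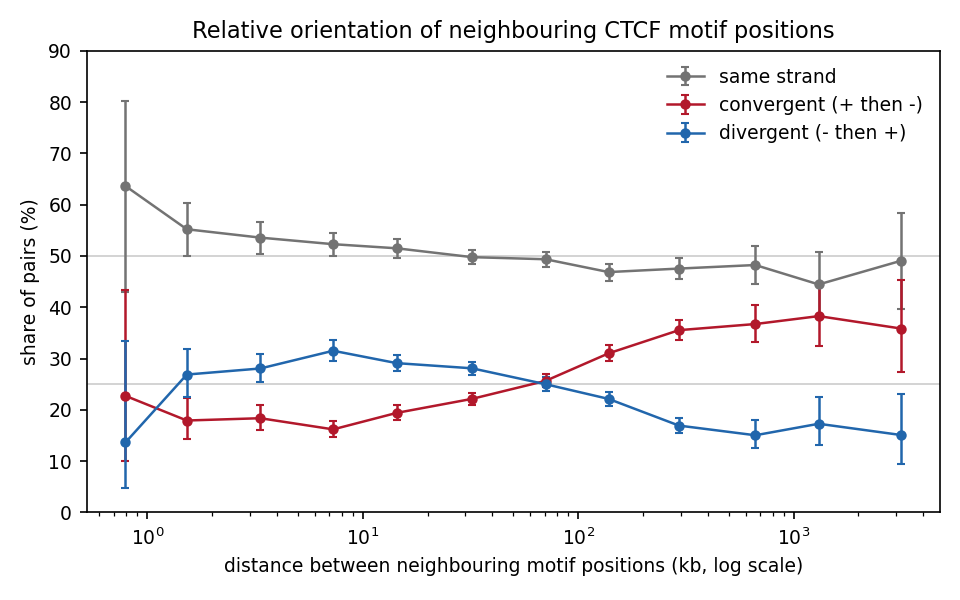
Share of neighbouring pairs (percent, vertical axis) on the same strand, convergent or divergent, against the distance between the motifs (kb, log axis) in 12 distance ranges, error bars 95% Wilson intervals; grey lines mark 25% and 50%. Divergent pairs exceed convergent ones from 1 to 50 kb, both lie near 25% at 50 to 100 kb, and convergent pairs lead beyond 100 kb.

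The same contrast appeared when switches of strand were counted from each kind of starting site, a test chosen after seeing the data. In the planted simulations this test did not call the unplanted range. Those simulations set each strand from the site before and the distance to it. Carry-over between ranges through the distance that follows a site is therefore not excluded. From 1 to 10 kb, 38.9% of plus sites (n = 1440) were followed by a minus site, whereas 53.4% of minus sites (n = 1850) were followed by a plus site, a difference of -14.5 points (Fisher's exact test, two-sided, adjusted p = 3.92e-16). From 100 kb to 1 Mb the values were 58.5% (n = 3758) and 45.2% (n = 2843), a difference of 13.3 points (Fisher's exact test, adjusted p = 5.47e-26). The difference was -3.86 points at 10 to 100 kb (Fisher's exact test, adjusted p = 3.25e-05) and 17.6 points over 1 Mb (adjusted p = 0.0017 by the same exact test). Put as distances, the same contrast was that divergent neighbours lay closer. Their median was 38.3 kb, against 72.0 kb for convergent neighbours and 46.5 kb for neighbours on the same strand.

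From 1 to 10 kb divergent pairs outnumbered convergent ones on 22 of 23 chromosomes (1 to 22 and X), the exception being chromosome 21 with 8 convergent and 6 divergent pairs. Chromosome 13 (8 convergent, 9 divergent) and chromosome X (7 convergent, 8 divergent) were near ties. The Wilson intervals of chromosomes 10, 11, 16 and 18 also included 50%. From 10 to 100 kb divergent pairs outnumbered convergent ones on all of the 23 chromosomes except chromosome 19, which had 198 convergent and 167 divergent pairs (54.2% convergent, 95% Wilson interval 49.1% to 59.3%). From 100 kb to 1 Mb convergent pairs outnumbered divergent ones on 22 of 23 chromosomes. The exception here was again chromosome 19, the densest, with 29 convergent and 31 divergent pairs (48.3%, 95% Wilson interval 36.2% to 60.7%), so that its share did not rise from the second range to the third. Chromosome 22 had the highest share at this distance, 79.5% (64.5% to 89.2%; 31 convergent, 8 divergent), followed by chromosome 20 with 71.8% (61.4% to 80.2%). Whether chromosomes differ from each other was not tested.

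**Figure D3:**
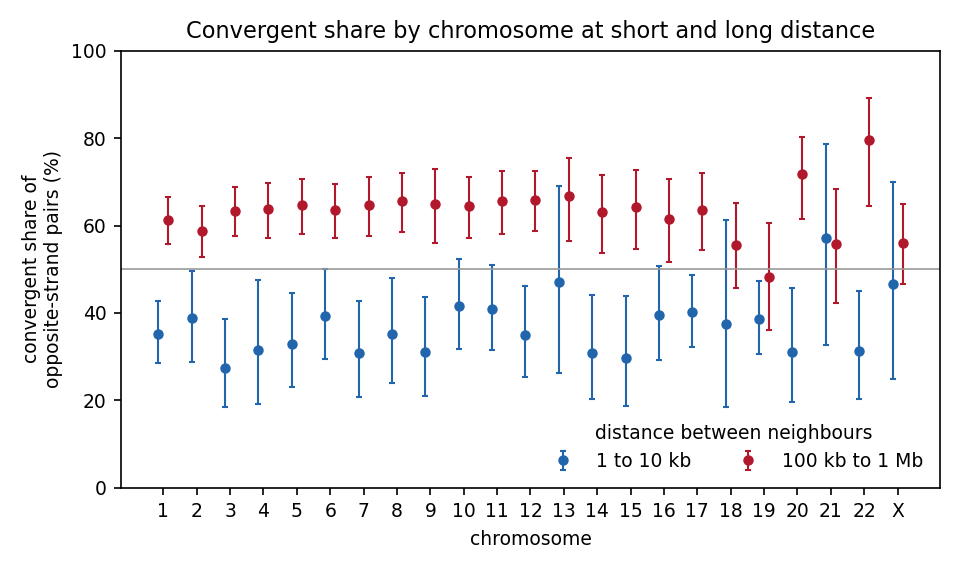
Convergent share of opposite-strand neighbouring pairs (percent) on each chromosome at 1 to 10 kb (blue) and at 100 kb to 1 Mb (red), error bars 95% Wilson intervals, horizontal line at 50%. The red point lies above the blue one on 22 of 23 chromosomes, the exception being chromosome 21.

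Neighbours on the same strand made up 49.6% of all 22619 pairs, which did not differ from shuffled strands (permutation p = 0.25). In the 5 distance ranges, tested for this share after seeing the data, it passed the test above the shuffled mean from 1 to 10 kb and below it from 100 kb to 1 Mb. It was 53.0% from 1 to 10 kb (95% Wilson interval 51.3% to 54.7%; permutation adjusted p = 0.0016), 50.0% from 10 to 100 kb (permutation adjusted p = 0.91) and 47.3% from 100 kb to 1 Mb (46.0% to 48.5%; permutation adjusted p = 1e-04). The shuffled mean was 50.0% in each of these 3 ranges. The 63.6% of the 22 pairs under 1 kb (43.0% to 80.3%; permutation adjusted p = 0.26) and the 45.8% of the 349 pairs over 1 Mb (40.7% to 51.1%; permutation adjusted p = 0.20) did not pass the test.

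The densest 100 kb windows held 10 or 11 sites, against a median of 1 in the windows of a fixed 100 kb grid that held any. Of the 5, 4 had 11 sites. The first lay on chromosome 7 from 38358600 to 38438513 (4 plus, 7 minus). The second, on chromosome 17 from 61912328 to 61996765, had 7 plus and 4 minus sites, and its last 6 sites were all on the plus strand. Chromosome 19 held 2 of them, from 1194667 to 1279891 (3 plus, 8 minus) and from 12868543 to 12958585 (4 plus, 7 minus). The fifth, with 10 sites, lay on chromosome 1 from 154971963 to 155067061 and had 5 sites on each strand. Genes in these windows are not named, since no hg19 annotation was used here.

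**Figure D4:**
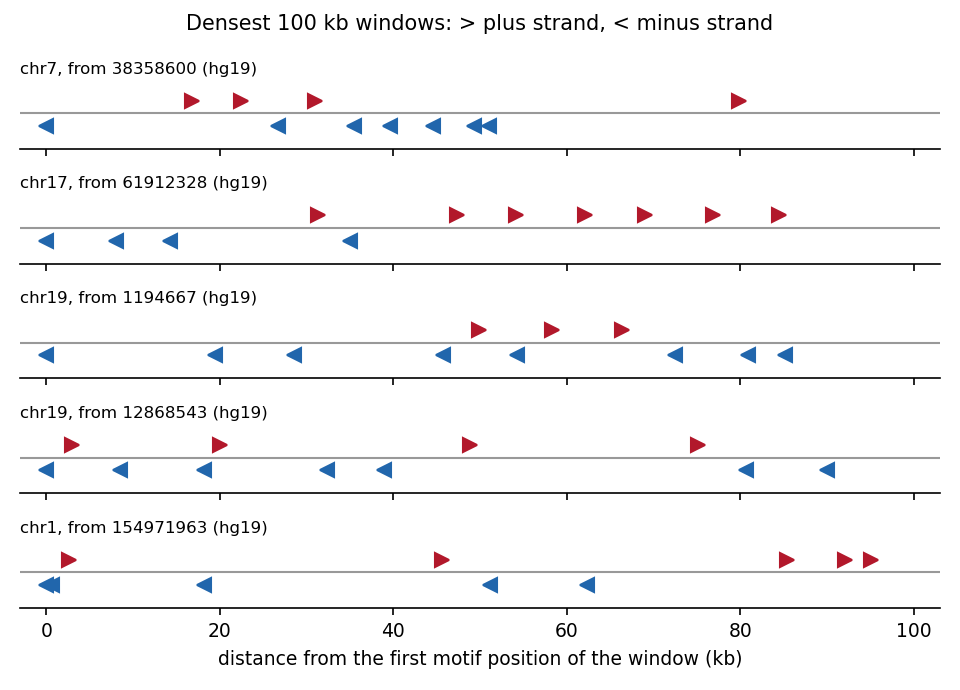
Map of the 5 densest 100 kb windows (hg19), each arrowhead a motif position at its distance in kb from the first position of the window, red and above the line for the plus strand, blue and below for the minus strand. The windows hold 11, 11, 11, 11 and 10 positions.

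The widest stretches without a site were on chromosome 9 from 44227460 to 66458325 (22.2 Mb), on chromosome 1 from 121189363 to 142585840 (21.4 Mb) and on chromosome 16 from 34666632 to 46588437 (11.9 Mb). These 3 span centromeres and the heterochromatin beside them, which hg19 leaves largely unsequenced. The next were both on chromosome X, from 83984923 to 92677879 (8.69 Mb) and from 140000760 to 147214826 (7.21 Mb).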

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

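Of 46 alternative values, 42 kept their direction and side of the threshold, or, for counts, stayed within 1.5 times. No listed positions overlapped, so merging overlapping positions moved nothing. Leaving out pairs under 1 kb could not change a convergent share in the ranges from 1 kb upwards. Nor could leaving out pairs over 500 kb change a share in the ranges up to 100 kb. These values are among the 42 but say nothing about stability. Over all distances the convergent share became 48.97% once pairs over 500 kb were left out, and then passed the permutation test at the smallest p that 100000 shuffles can give, 1e-05, since more convergent than divergent pairs lay beyond that distance. Sites with a second site nearby numbered 4 at 500 bp and 730 at 2 kb, against 44 at 1 kb. For the 22 pairs under 1 kb, the switch rates from plus and from minus, compared after seeing the data, differed by -1.79 points, opposite in sign to the convergent share and far from any call (Fisher's exact test, adjusted p = 1). The convergent shares from 1 kb upwards passed the test under each alternative that gave a test; from 100 kb to 1 Mb the share was 62.2% without pairs over 500 kb and 63.3% on autosomes. Leaving out each chromosome in turn, also chosen after seeing the data, gave 35.8% to 36.6% at 1 to 10 kb and 62.9% to 63.5% at 100 kb to 1 Mb. No paired analysis was possible because the list carries no libraries. Keeping 1 position per peak was not run, since the list has no peak identifiers, and the alternatives for transcription starts, gene lists, density per chromosome length and library signal were not run, for want of an hg19 reference or of values per library.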

Other observations

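The tests in this part were chosen after the patterns had been seen, except the shuffles of adjacent neighbours by distance, which were planned, and the chains of strands, which were set up before their outcome was known. Strands also departed from the shuffles for sites that were not adjacent. Sites 2 places apart along the chromosome were on the same strand in 48.7% of 22595 pairs, against 50.0% with shuffled strands (SD 0.333 points; permutation adjusted p = 0.00044), and the share was under 50% on 19 of 23 chromosomes. Sites 3 places apart gave 49.0% (permutation adjusted p = 0.0049; 16 of 23 chromosomes), whereas sites 4 and 5 places apart gave 50.2% and 49.6% and did not pass the permutation test (adjusted p = 0.59 and 0.29). Leaving out any 1 chromosome kept the share between 48.6% and 48.8% at 2 places.

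The rise of the convergent share with distance was weighed against 3 technical explanations, of which 1 stays open. Chance assignment of strands is argued against by the shuffles, whose largest adjusted p from 1 kb to 1 Mb was 1.25e-05. Differences between chromosomes in site density are argued against by the order within chromosomes, since the 100 kb to 1 Mb share exceeded the 1 to 10 kb share on 22 of 23. The shuffles stayed within chromosomes and kept all positions, so they had already allowed for such differences. The count of 22 restates the pattern by chromosome and is not separate support. Selection upstream among closely spaced positions stays open. Among opposite-strand pairs from 100 kb to 1 Mb whose sites had no other listed site within 10 kb, 60.9% were convergent (1652 convergent, 1059 divergent; lower 95% Wilson bound 59.1%), but the list holds only positions left after any selection, so a site whose neighbours were discarded also looks isolated and the bound set for this test decides nothing. A candidate explanation is the known arrangement of loop and domain borders, with motifs facing each other across a domain and away from each other at a border. It applies only if plus then minus means motifs facing each other, which rests on the motif matrix direction that is not given. Contact maps were not used here and no biological explanation was tested.

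Sites under 1 kb apart were rare. The list held 22 such neighbouring pairs, whereas 1000 uniform random placements between the first and last site of each chromosome gave 197 on average and never fewer than 157, which argues against random placement. From 1 to 2 kb the relation turned, with 346 pairs against 194 placed (ratio 1.78), and from 5 to 10 kb there were 1964 against 918 (ratio 2.14). Uniform placement also missed the longer spacings. From 100 kb to 1 Mb there were 6601 pairs against 9878 (ratio 0.668), and over 1 Mb 349 against 44 (ratio 7.94). It also put sites into the widest stretches that hold none. Ratios above 1 are therefore not particular to 1 to 2 kb. The abrupt change at about 1 kb may come from an upstream choice of 1 position per peak or from merging of nearby peaks, which the ratio of 1.78 allows, but the peaks behind the list were not used here. This explanation therefore cannot be told apart from a true shortage of closely spaced bound motifs.

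The excess of opposite strands at 2 places was set against chains built from adjacent neighbours alone. In 1000 chains of strands drawn from the switch rates of adjacent sites in 12 distance ranges, the share on the same strand at 2 places averaged 50.1% and ranged from 49.1% to 51.2%. The observed 48.7% lay outside (two-sided p = 0.001 from the simulated chains, the smallest that they can give), so adjacent orientation by distance did not account for it, and neither did chance (permutation adjusted p = 0.00044). At 3 places the observed 48.98% was also below the lowest of the 1000 chains, 49.01% (mean 50.1%).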
